A study of Mus musculus with 8 samples.

How the data were processed

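Gene expression was measured in 8 primary mouse osteosarcomas, 4 of the shRNA OS model and 4 of the Cre:lox OS model. Per the labels, tumours were homogenised in Trizol and RNA was purified on RNeasy columns, labelled with biotin and hybridised to 1-colour arrays. The deposited values are log2 expression values that the authors computed with RMA (robust multi-array average), per the submitters' processing notes, which also name the genome build mm9. The version of RMA and any filter are not given in the sources used here. From the values, the scale is log2 of intensity: each array held 35556 values between 2.53 and 14.57, none missing. The 8 arrays did not share 1 distribution, so the interquartile range differed, from 2.59 to 3.19. Differences in value range between arrays can therefore enter every comparison.

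Groups came from the model given in the labels. The titles give each tumour its own number, so replicates were taken as separate tumours, and p-values measure the spread between tumours. Replicates were numbered in accession order and pair no samples. No 2 arrays held identical values, and the 28 pairwise correlations ran from 0.924 to 0.983. The labels give no batch and no sex.

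Probe sets were named from the platform annotation paired with the values. Of 35556 probe sets 21789 had 1 gene symbol, 1621 had several and 12146 had no listed gene. Only those with 1 symbol were used. A gene with several probe sets was represented by that with the highest mean over the 8 arrays, which gave 19938 genes. The reference gene table (GRCm38.p6) held the gene ID of 21698 of the 21789 probe sets, and its symbols did not differ. As it is of another build than mm9, it was used only for names and for which genes neighbour each other. For Fabp5, Ago2 and Pgk1 several probe sets were measured, and they differed in the same direction.

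Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on the deposited log2 values, with Benjamini-Hochberg adjustment and a threshold of 0.05. No filter on dim genes was applied. The comparison of models had no covariate, and those of Rb genotype and of tumour site had the model as a covariate. Tests of whether the effect of Rb genotype or of site differed between models rest on single tumours and are not read here. Each model held 1 Rb+/+ tumour, and 3 of the 4 shRNA OS tumours were tibial. In simulated data with the real means and spreads, the comparison of models recovered 53 of 100 genes changed 2-fold and 89 of 100 changed 4-fold, with 5 false calls among 19938 genes. Genes were drawn independently there, and 200 were changed at once, which eases the adjusted threshold. These rates are therefore not the power of the real comparison. With 3 of the 28 lists shifted by 0.5 and independent genes, camera called those 3 and no other.

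Before the data were examined, 28 gene lists were fixed, 17 of pathways and lineages and 11 of cell types. The 17 were osteoblast differentiation and bone matrix, osteocyte, fibroblast, chondrocyte, adipocyte, p53 target, E2F target and DNA replication, mitosis, Wnt target and antagonist, Hedgehog target, Notch target, TGF-beta and BMP response, interferon response, microRNA and small-RNA machinery, hypoxia and glycolysis, matrix metalloproteinase, and immediate early and heat shock. The 11 were osteoclast, macrophage, neutrophil and granulocyte precursor, erythroid, T and NK cell, B cell, MHC class II, endothelial, smooth muscle and pericyte, skeletal muscle, and epidermis. Of 402 members 373 were measured. Lists were tested with limma's camera at its preset correlation of 0.01, which compares the list with all other genes, with camera's estimated correlation and with fry as alternatives. An exact 2-sided permutation test of each list's mean over the 70 arrangements, and the list tests for Rb genotype and site, were chosen after seeing the data.

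The genes named were also set by a rule before the data were examined. They were the p53 gene, Rb1, Cdkn1a and Mdm2, of which the p53 gene and Cdkn1a were not among the genes tested. Added to these were up to 10 genes per direction past the threshold whose groups did not overlap, filled to 5 per direction with those of smallest p. The leading member of each list was also named. For Rb genotype and site the genes named were the 2 of smallest p per direction. Symbols ending in Rik or starting with Gm or LOC, receptor and immunoglobulin segments, Y-linked genes and Xist were counted and not named, with the exception of A930017M01Rik. The planned comparison of the p53 transcript, and genes read only by probe sets with several symbols, are not analysed here.

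Alternatives were quantile normalization, median centring, 2 filters on dim genes, the mean of probe sets, every probe set, eBayes with trend and robust, array weights, Rb genotype or site as a covariate or none, only Rbfl/+ or only tibial tumours, 2 other thresholds, and leaving out each tumour in turn. Neighbouring genes were examined in 388 non-overlapping runs of 50 genes, using 19400 genes placed on the autosomes and the X chromosome. For each tumour the median of a run was taken over its genes, each set against its mean over the 8 tumours and each tumour against its own median, and compared with 100 shuffled gene orders. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.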

Results

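Osteosarcoma is a malignant tumour of bone-forming cells. RNA levels were measured on 8 arrays, each holding RNA from a separate primary osteosarcoma of a C57Bl6 mouse. In 4 tumours, called shRNA OS, p53 was targeted by a transgenic short hairpin RNA (p53.1224). The other 4, called Cre:lox OS, carried floxed p53 alleles. Each model held 3 tumours with 1 floxed Rb allele (Rbfl/+) and 1 Rb+/+ tumour. The tibia was the site of 3 shRNA OS and 2 Cre:lox OS tumours, and the other 3 tumours came from the humerus (2) and the scapula (1). Each array gave 35556 log2 values with medians between 7.13 and 7.23, and the number of arrays limited the precision. The array of shRNA OS replicate 2 stood apart, with a mean correlation of 0.941 with the other 7 against 0.961 to 0.968 for the rest.

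The comparison of the models asks whether osteosarcomas arising with a p53 hairpin differ in expression from those arising with floxed p53 alleles. In shRNA OS, 3 genes rose and 1 fell among 19938 genes. Xlr, a member of an X-linked multigene family first described in lymphocytes, rose by 2.58 on the log2 scale (SE 0.29), with 8.79 ± 0.47 against 6.21 ± 0.51 (log2, SD, n = 4 each). Pax6, a transcription factor of eye and brain development, rose by 1.53 (SE 0.15), with 7.97 ± 0.26 against 6.44 ± 0.07. Map1a, a microtubule-binding protein best known from neurons, fell by 1.38 (SE 0.14), from 7.96 ± 0.24 in Cre:lox OS to 6.58 ± 0.05. The remaining gene, A930017M01Rik, rose by 2.51 (SE 0.29) and is named after its values were seen.

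All 4 genes separated the 4 shRNA OS tumours from the 4 Cre:lox OS tumours, with limma adjusted p of 0.0321 for Pax6 and Map1a and 0.042 for Xlr and A930017M01Rik. Members of the Xlr family are similar in sequence, so which copy the Xlr probe set read is uncertain. The lower means of Xlr, Pax6 and Map1a lay below the array medians, and as signal over background was not analysed here no fold is given. A930017M01Rik lay in a stretch of 50 neighbouring genes of which 46 had a higher mean in shRNA OS. The next genes did not pass. Cenpv, Csrnp3 and Zswim5 had means 1.28, 1.93 and 1.75 higher in shRNA OS (adjusted p 0.0584, 0.0668 and 0.0668). Hal (-1.49), Armcx2 (-1.36), Fabp5 (-1.65) and Ranbp17 (-1.60) had lower means, with adjusted p between 0.0668 and 0.0683. An unadjusted p under 0.05 was reached by 1920 genes, of which 720 were higher and 1200 lower in shRNA OS, where chance gives 997. In 1084 genes (5.44%) the 2 models did not overlap, where chance gives 2.86%. The count of 4 ranged from 0 without shRNA OS replicate 3, shRNA OS replicate 4 or Cre:lox OS replicate 3 to 42 without shRNA OS replicate 1. It was 7 without shRNA OS replicate 2 and 19 without Cre:lox OS replicate 1. Without Cre:lox OS replicate 2 it was 1, A930017M01Rik. Without Cre:lox OS replicate 4 it was also 1, a gene that was none of the 4.

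**Figure D1:**
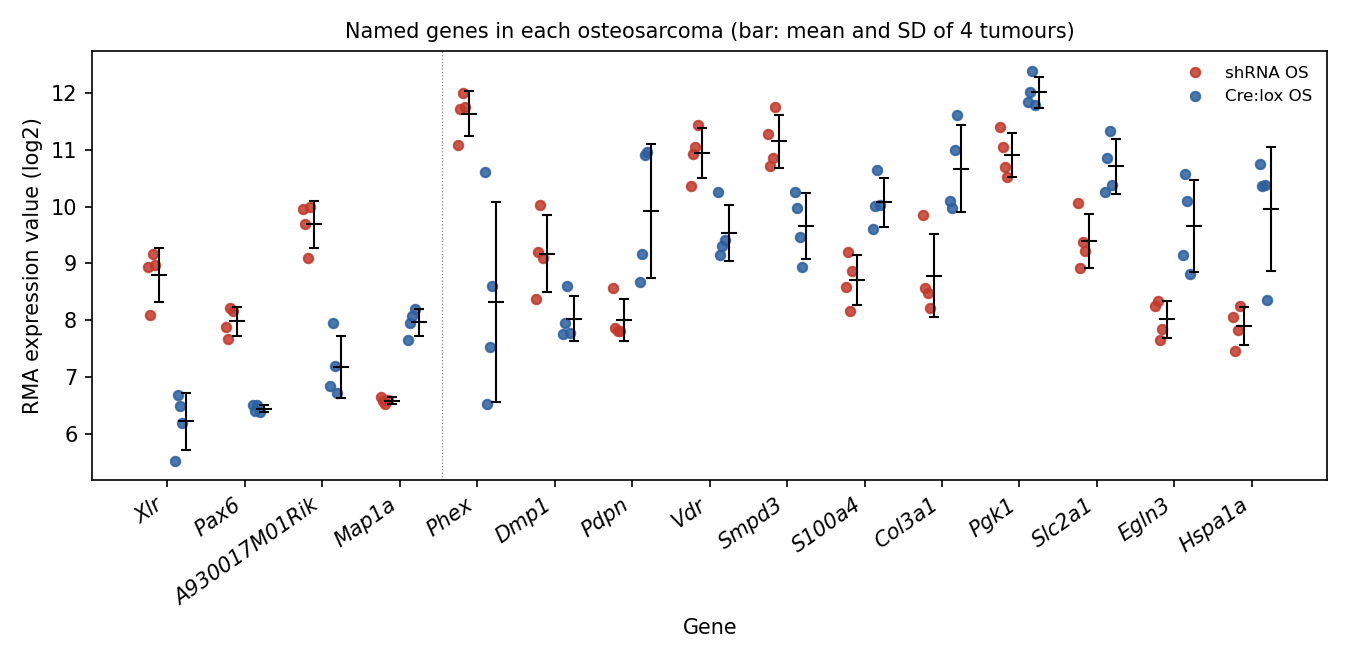
RMA expression values (log2, vertical axis) of 15 genes in each of the 4 shRNA OS (red) and 4 Cre:lox OS (blue) tumours. Points are tumours, and bars give the mean and SD of 4 tumours. The 4 genes left of the dotted line passed the test over all genes, and the others did not. Phex lay between 6.52 and 10.62 in Cre:lox OS and above that in all 4 shRNA OS tumours.

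Genes of bone-forming cells had higher means in shRNA OS. Among 18 measured members of the osteoblast differentiation and bone matrix list, 15 were higher on average and 3 lower, with a mean difference of 0.38. Vdr, the vitamin D receptor, was higher by 1.41 (SE 0.29), and Smpd3, a sphingomyelinase needed for bone mineralisation, was 2.83-fold higher. Vdr and Smpd3 passed when adjusted over the list alone (adjusted p 0.00788 each), and none of the 18 passed over all genes. Postn, which encodes the matrix protein periostin, went the other way at -1.69. With limma's camera at its preset correlation the list had adjusted p = 7e-04, and adjusted p = 0.573 with an estimated correlation. An exact 2-sided permutation test of the list mean gave p = 0.0286, the smallest that 70 arrangements allow, and 0.343 after adjustment over 28 lists.

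Of 9 osteocyte genes, 7 had higher and 2 lower means in shRNA OS. Adjusted over the list alone, 5 were higher: Phex by 3.32 (SE 0.72), Dkk1 by 2.05, Sost by 1.18, Dmp1 by 1.15 and Irx5 by 0.81. Phex encodes a peptidase whose loss causes X-linked hypophosphataemia, Sost encodes the Wnt antagonist sclerostin, and Dmp1 encodes an acidic matrix protein of mineralised tissue. Pdpn (-1.92) and Ackr3 (-0.77) were lower adjusted over the list alone, and Pdpn marks early rather than late osteocytes. None of the 9 passed over all genes, where Phex had adjusted p = 0.192. The list as a whole missed camera's threshold (adjusted p = 0.0556, and adjusted p = 0.573 with an estimated correlation). Members named for this and the other lists beyond the one of smallest p were chosen after their values were seen.

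Hypoxia and glycolysis genes had lower means in shRNA OS, 12 of 14 members, with a mean difference of -0.56. Adjusted over the list alone, 5 were lower: the glucose transporter Slc2a1 (-1.32), the glycolytic enzymes Pgk1 (-1.10, SE 0.22) and Hk2 (-0.80), the oxygen sensor Egln3 (-1.64) and the mitophagy receptor Bnip3 (-0.83). Camera's adjusted p was 2.19e-05 at the preset correlation, and adjusted p = 0.573 with an estimated correlation. Fibroblast genes were lower in 18 of 21 members, with a mean difference of -0.58. S100a4 (-1.37, SE 0.27), the extracellular matrix gene Fbln1 (-1.56) and the collagen gene Col3a1 (-1.89) passed over the list alone. For this list camera's adjusted p was 5.49e-05, and adjusted p = 0.573 with an estimated correlation. Immediate early and heat shock genes were lower in 10 of 11 members, with a mean difference of -0.53. Hspa1a, which encodes the inducible heat shock protein 70, stood at -2.06 (SE 0.46), and the AP-1 genes Jun (-0.75) and Junb (-0.48) and Ier3 (-0.87) also passed over the list alone. Camera's adjusted p was 2.8e-04, and adjusted p = 0.573 with an estimated correlation. These genes also respond to the handling of tissue, on which the labels give no detail. No member of the 3 lists passed over all genes.

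Matrix metalloproteinase genes and their inhibitors had a mean difference of -0.43, with 10 of 14 members lower. Mmp19 (-1.19, SE 0.21) and the inhibitor gene Timp1 (-1.31) were lower and Mmp16 (0.89) was higher when adjusted over the list alone. Camera gave adjusted p = 0.0158, and adjusted p = 0.573 with an estimated correlation. The call was lost without shRNA OS replicate 1 or Cre:lox OS replicate 4 (adjusted p up to 0.137). Cre:lox OS replicate 4 held the highest values of the neighbouring genes Mmp3 and Mmp13.

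Genes of cell division had lower means in shRNA OS. In the E2F target and DNA replication list 22 of 24 members were lower, with a mean difference of -0.29. Only Pola1, a subunit of DNA polymerase alpha, passed over the list alone (-0.65, SE 0.15). Camera gave adjusted p = 1.51e-04, and adjusted p = 0.694 with an estimated correlation. In the mitosis list 18 of 20 members were lower, with a mean difference of -0.25, and none passed over the list alone. Its smallest p belonged to Ndc80 (-0.44). Camera gave adjusted p = 0.0158, and adjusted p = 0.794 with an estimated correlation. The mitosis call was lost without shRNA OS replicate 2 or 4 or Cre:lox OS replicate 1 or 2, with adjusted p up to 0.311.

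Markers of other cell types also differed between the models on average. All 15 macrophage genes had lower means in shRNA OS, with a mean difference of -0.62, led by Itgam (-1.03). Camera gave adjusted p = 8.5e-04, and adjusted p = 0.694 with an estimated correlation. All 6 MHC class II genes had higher means, with a mean difference of 0.76, led by Cd74 (1.33), the invariant chain. Camera gave adjusted p = 0.0075, and adjusted p = 0.694 with an estimated correlation. All 14 skeletal muscle genes had lower means, with a mean difference of -0.80, led by the myosin light chain gene Myl1 (-1.82), and a score SD of 1.38 within shRNA OS and 1.19 within Cre:lox OS. Camera gave adjusted p = 0.0158, and adjusted p = 0.794 with an estimated correlation. No gene of these 3 lists passed over the list alone. The macrophage call was lost without shRNA OS replicate 4 or Cre:lox OS replicate 4 (adjusted p up to 0.056), and the MHC class II call without shRNA OS replicate 1 or Cre:lox OS replicate 2 (up to 0.162). The muscle call was lost without shRNA OS replicate 1, 2 or 4 or Cre:lox OS replicate 1 or 3 (up to 0.311).

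**Figure D2:**
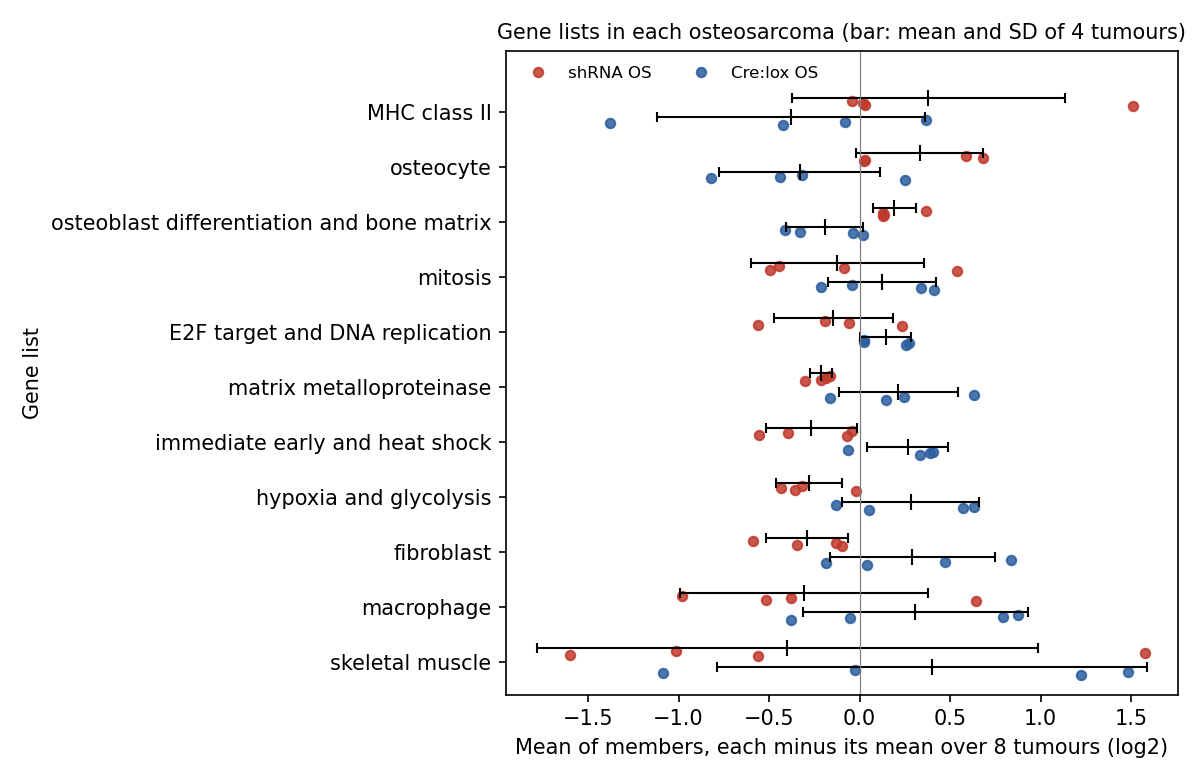
Mean of the members of each gene list, each member set against its own mean over the 8 tumours (log2, horizontal axis), in 4 shRNA OS (red) and 4 Cre:lox OS (blue) tumours. Points are tumours, and bars give the mean and SD of 4 tumours. The osteoblast list separated the models. The shRNA OS mean was -0.28 for hypoxia and glycolysis genes and -0.40 for skeletal muscle genes, and the muscle list spread most within both models.

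In all, 10 of the 28 lists passed camera at its preset correlation, 2 higher and 8 lower in shRNA OS. This balance was not kept without dim genes: above the 25th percentile of level 4 lists were higher and 5 lower, and above the median level 5 were higher and 5 lower, with 7 of the 10 kept in each. None passed with an estimated correlation, for which the smallest adjusted p was 0.573, and none passed fry's test of a shift in 1 direction (0.273). Fry's test of change in either direction passed 5 lists at adjusted p = 0.0226, namely hypoxia and glycolysis, fibroblast, matrix metalloproteinase, osteocyte, and microRNA and small-RNA machinery. The last was 0.04 by median and -0.03 by mean, with camera's direction down. In it Ago2, the slicing Argonaute protein of RNA interference, lies in a run of neighbouring genes shifted in shRNA OS replicate 2. Ago2 was higher by 0.80 (SE 0.19) adjusted over the list alone. Smad6 (0.94), an inhibitor of BMP signalling, was higher in the TGF-beta and BMP list and Gli3 (-0.80) lower in the Hedgehog list on the same basis. No list not named so far had a member that passed over the list alone.

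The p53 target list had a mean difference of -0.06 (camera adjusted p = 0.611), with Gadd45a at -0.56 and Mdm2 at 0.28. Further mean differences were 0.27 for endothelial genes (Tek 1.01), 0.12 for chondrocyte genes (Acan -1.49), -0.35 for Wnt targets and antagonists (Sfrp2 -1.66), -0.22 for Hedgehog targets, -0.08 for Notch targets (Notch1 -0.34) and -0.18 for TGF-beta and BMP responses. They were 0.10 for B cell genes (Ebf1 0.89), 0.05 for T and NK cell genes (Il7r -0.45), 0.08 for erythroid genes (Car1 0.81), 0.10 for osteoclast genes (Clcn7 -0.39) and 0.04 for smooth muscle and pericyte genes (Acta2 1.44). For adipocyte genes the mean difference was -0.045 (Lpl -0.33). Epidermis genes (-0.09, Trp63 -0.61), neutrophil and granulocyte precursor genes (-0.04, Mmp8 -0.51) and interferon response genes (-0.02, Rsad2 0.76) had medians of the opposite sign to their means, and camera's direction followed the mean for epidermis and the median for the other 2. None of these lists passed camera, with adjusted p from 0.0503 for the endothelial list to 0.984 for the interferon list.

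The Rb comparison asks whether tumours with 1 floxed Rb allele differed from Rb+/+ tumours, with the model as a covariate. Rb1 itself was 9.40, 9.54, 9.17 and 9.15 in shRNA OS replicates 1 to 4 and 9.34, 9.31, 9.10 and 9.71 in Cre:lox OS replicates 1 to 4. Its difference, Rbfl/+ minus Rb+/+, was -0.13 (SE 0.20, adjusted p = 0.894), and -0.05 between the models. Whether its probes lie in the floxed part is not known here, so these values check no label. No gene passed limma's test over 6 and 2 tumours, with 943 genes at an unadjusted p under 0.05 where chance gives 997. The smallest p values belonged to Pmp22 (1.27) and Snx3 (0.92), higher in Rbfl/+, and to Akr1c12 (-0.79) and Nrgn (-1.32), all with adjusted p = 0.836. Of the lists, macrophage genes (0.60) and E2F targets (0.20) were higher and endothelial genes (-0.37) lower in Rbfl/+ at camera's preset correlation, with adjusted p = 0.858 for each with an estimated correlation. The count of 3 lists became 10 without Cre:lox OS replicate 2, 5 without shRNA OS replicate 3 or Cre:lox OS replicate 4, and 1 without Cre:lox OS replicate 3. Leaving out shRNA OS replicate 2 or Cre:lox OS replicate 1 left 1 Rb+/+ tumour. The spread then came from the Rbfl/+ tumours alone, so those counts are not read. Of the 2 Rb+/+ tumours 1 was shRNA OS replicate 2, whose array stood apart. Its E2F target score was -0.56, against 0.26 in Cre:lox OS replicate 1, so the 2 Rb+/+ tumours did not share the E2F difference.

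The labels also give the bone of each tumour, and tibial tumours were set against those of the humerus and scapula with the model as a covariate. No gene passed limma's test over 5 and 3 tumours, with 1125 genes at an unadjusted p under 0.05. Lum, which encodes the collagen-binding proteoglycan lumican, was 2.78 higher in tibial tumours (SE 0.29), with 10.30 ± 0.52 (SD, n = 5) against 7.77 ± 0.88 (SD, n = 3) and limma adjusted p = 0.104. Col6a1 (1.26), Vsnl1 (-1.47) and Pparg (-1.44), the nuclear receptor of fat cell differentiation, followed with adjusted p = 0.375. Lum passed without Cre:lox OS replicate 2 (3.08, adjusted p = 0.0238), and without shRNA OS replicate 4 Crabp2 passed (2.98, adjusted p = 0.0457, named after its values were seen).

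At camera's preset correlation 12 lists passed between sites, 8 higher and 4 lower in tibial tumours, and none with an estimated correlation (smallest adjusted p = 0.234). The balance was 6 higher and 7 lower without Cre:lox OS replicate 2, 8 and 7 without shRNA OS replicate 1, and 8 and 8 with no covariate. Macrophage genes (0.98), MHC class II genes (0.84), skeletal muscle genes (0.73), fibroblast genes (0.59), interferon response genes (0.56), Wnt targets and antagonists (0.39), T and NK cell genes (0.24) and matrix metalloproteinase genes (0.22) were higher on average in tibial tumours. Osteoclast genes (-1.001), Hedgehog targets (-0.54), adipocyte genes (-0.32) and osteoblast genes (-0.31) were lower. At that correlation 6 lists passed by site as well as by model: osteoblast, macrophage, fibroblast, MHC class II, skeletal muscle and matrix metalloproteinase.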

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

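In this part, the tests of Rb genotype and of other cell types as explanations for the array that stands apart were chosen after the result was seen. In each model, the most distant of 4 tumours was set against the other 3 for each named gene, each list and 4 array measures. Its gap to the nearest was called large when it passed Dixon's criterion, which chance passes in about 1 in 20 groups. This held in 11 of 160 tests, where chance gives about 8.

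The array of shRNA OS replicate 2 had a mean correlation of 0.941 with the other 7 arrays, far below the 0.968 of the other 3 shRNA OS tumours, and the narrowest interquartile range (2.59 against 2.79 to 3.19). A narrower value range alone is argued against by the mean rank correlation, which no such change of scale can move: it was 0.934 for this tumour and 0.958 to 0.966 for the other 7. The other Rb+/+ tumour, Cre:lox OS replicate 1, did not stand apart, with a mean correlation of 0.968. As this is 1 tumour, of the other model, it cannot decide whether the Rb+/+ genotype had a part. More cells of another type stay open: of the 11 marker lists 0 were highest in this tumour, but that also held for Cre:lox OS replicates 2 and 3. Among cartilage genes, chosen after their values were seen, Col2a1 was 10.11 against 7.77 to 8.64 in the other 7, while Acan was the lowest at 5.82. RNA quality and a biological difference of this tumour were not tested and stay open too.

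The same tumour had the lowest mean of microRNA and small-RNA machinery genes within its model, -0.20 against 0.03 to 0.07 in the other 3, and the lowest Pmp22, 10.18 against 11.52 to 11.78. Pmp22 was named for its small p by Rb genotype, and this tumour is the only Rb+/+ tumour of its model. That choice favours such a gap, so the chance rate does not hold for Pmp22. The MHC class II score was 1.51 in shRNA OS replicate 1 and -0.04 to 0.03 in the other 3. In the same tumour Car1 was 6.36, against 7.86 to 8.06. In Cre:lox OS replicate 3 Car1 was 7.52, against 6.46 to 6.52. The osteoblast list score was 0.37 in shRNA OS replicate 4 and 0.13 to 0.14 in the other 3, and Sfrp2 was 10.35 in shRNA OS replicate 3 against 8.19 to 8.33. Cre:lox OS replicate 4 had the lowest immediate early and heat shock score, -0.0668 against 0.33 to 0.41, and the lowest Hspa1a, 8.35 against 10.36 to 10.74. It also had the highest Armcx2, 10.04 against 9.48 to 9.52.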

How the results depend on the processing

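The exact permutation test of list means, and the list tests for Rb genotype and site, were chosen after seeing the data. The count of 4 genes between models was 8 with quantile normalization (5 higher, 3 lower), 2 with median centring (1 higher, 1 lower), 0 among genes above the median level, 0 over every probe set, 19 with array weights, 13 with site as a covariate, 9 in Rbfl/+ tumours, 2 in tibial tumours and 24 at adjusted p under 0.1. The 2 in tibial tumours were both lower in shRNA OS, and neither was among the 4. Leaving out each tumour gave 0 to 42. Xlr, Pax6 and Map1a kept their direction in every alternative that measured them, and each passed in 3 of 8 runs with 1 tumour left out. The cause was not tested, except that the filter above the median level removed Xlr, Pax6 and Map1a, and every probe set meant more tests. The count of 10 lists was 8 to 12 under other settings of camera (4 higher and 8 lower with median centring, 4 and 5 above the 25th percentile of level, 5 and 5 above the median level, 5 and 7 in tibial tumours), but 0 with an estimated correlation, 0 with fry's test of a shift in 1 direction (its test of change in either direction passed 5) and 0 in the exact permutation test. Rb1 by Rb genotype ranged from -0.30 to 0.0373 without each tumour in turn and passed in none, and no gene passed by Rb genotype in any alternative. Genes by site numbered 0, or 1 without shRNA OS replicate 4 or Cre:lox OS replicate 2. Among 556 alternatives of single lists 447 kept direction and side of the threshold, 39 turned direction without passing before or after, and 2 turned with a call. The mitosis mean became 0.11 in tibial tumours, where it did not pass, and the interferon mean 0.38 without Cre:lox OS replicate 4, where it passed, within -0.31 to 0.38 over the left-out tumours. Among 882 alternatives of named genes 836 kept both, 4 turned without passing and none turned with a call. No paired analysis was possible because the tumour numbers in the labels differ between the models. The alternatives planned for the p53 transcript were not run. Signal over background was not analysed here.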

Other observations

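In this part, the test of the genes from Vps13b to A930017M01Rik over other splits of the tumours, and the choice of runs and genes named, came after the values were seen. In Cre:lox OS replicate 4 a run of 50 neighbouring genes stood far above the other tumours. Birc2, an inhibitor of apoptosis, was 11.24 there and 7.51 to 7.91 in the other 7, and its neighbours Yap1, the Hippo pathway effector (12.24 against 9.55 to 9.88), Birc3 (11.05 against 7.77 to 9.01), Cwf19l2 (10.54 against 7.26 to 7.91) and Dcun1d5 (11.52 against 8.72 to 9.26) went with it. The matrix metalloproteinase genes of the same run went both ways. Mmp3 was 9.36 against 5.19 to 6.47 and Mmp13 was 13.70 against 11.19 to 13.41, but Mmp12 was the lowest of the 8 at 7.47 against 7.54 to 10.17, and Mmp10 was 7.31 there and 8.77 in Cre:lox OS replicate 1. Mmp8, also of the matrix metalloproteinase list, was highest in this tumour at 6.96 against 5.19 to 5.85. Of the 50 genes in the run 33 were highest in this tumour.

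Other tumours held runs of their own. In shRNA OS replicate 3 the run from Nlrp9c to Med29, which holds the kinase gene Akt2, had a median of 0.74, against -0.21 to 0.10 elsewhere. In shRNA OS replicate 1 the run from Lyz2 to Marchf9 had a median of 0.57, against -0.24 to 0.11. It holds Mdm2, the ubiquitin ligase of p53, which was 9.63 there and 8.50 to 8.93 in the other 7. Hmga2 in the same run ranked 5 of 8. In Cre:lox OS replicate 1 the run from Insr to Naxd had a median of 0.53, against -0.18 to 0.10. In shRNA OS replicate 2 the run from Lratd2 to Lypd2 had a median of 0.82, against -0.31 to 0.24. In that run Ptp4a3 was 11.78 against 9.96 to 11.33, and Ago2 was 11.49 against 10.19 to 11.38, while Myc ranked 7 of 8. Dim genes were raised on this array (a median of 0.27 in the lowest quartile of levels). After quantile normalization, among genes above the median level, the overlapping run from Col14a1 to Zfp41 had 0.54, against -0.55 to 0.41.

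Such shifts of neighbouring genes appeared in all 8 tumours, in each of which the spread of run medians exceeded that of every one of 100 shuffled gene orders, by 2.48 to 3.12 times the median shuffle. Silent genes raised by a narrow value range are argued against as the whole cause, since among genes above the median level, after quantile normalization, the spread exceeded every shuffle in 8 of 8 tumours. With 1 gene per symbol stem in each run it did so in 8 of 8 as well. That cannot decide on neighbouring members of a gene family. Real runs that hold families then keep fewer genes than shuffled runs, which by itself widens the spread of their medians. A candidate explanation is gain or loss of DNA in single tumours. It was not tested, since DNA was not analysed here, and regulation shared by neighbouring genes stays open too.

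Between the models, the run from Vps13b to A930017M01Rik had medians of 0.05 to 0.55 in shRNA OS and -0.60 to -0.15 in Cre:lox OS. In it 15 of 50 genes, all higher in shRNA OS, did not overlap between models, among them Ebag9 (1.76, limma adjusted p = 0.0992). Chance stays open: 4 of the 35 splits of the tumours into 4 and 4 had a run with as many such genes, with up to 28 in another split. It does so for the 18 runs that separated the models too, as 7 of the 35 splits separated as many, with up to 46.

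Over the same 35 splits, only 1, the real split, gave 4 or more genes past the threshold, and the highest other gave 2. As 1 of 35 is the smallest share these splits allow, a chance split is an unlikely but not excluded source of that count. For the gene lists chance stays open: 12 of the 35 splits gave 10 or more lists at camera's preset correlation, with up to 14 in another split. Of the 10 lists, 8 kept their call and direction without shRNA OS replicate 2. Those calls did not rest on that array alone, and for the mitosis and skeletal muscle lists it stays open as the cause. The array had a share in the E2F target difference, as its score was -0.56, against 0.23, -0.06 and -0.19 in shRNA OS replicates 1, 3 and 4. With site as a covariate 10 kept their call and direction, but among the 3 and 2 tibial tumours alone only 7 did. For those 7 the call did not need uneven sites. For the E2F target, mitosis and MHC class II lists the tibial subset also dropped 3 tumours, so the lost calls cannot be laid to site. With the model as a covariate their site differences were -0.11, -0.10 and 0.84. Only the last passed camera at its preset correlation. Uneven sites are not excluded for these 3 lists. A kept call is weak evidence, as a median of 8 lists passed over the 35 splits. Between sites, the real split gave 0 genes, so all 56 splits into 5 and 3 gave as many. These splits had the model as a covariate, so tumours were compared within each model. The highest other gave 115, setting shRNA OS replicate 1 and Cre:lox OS replicates 3 and 4 against the rest of their models. The next set Cre:lox OS replicates 1, 2 and 3 apart. With the model as a covariate it compared them with Cre:lox OS replicate 4 alone, so no grouping is read from it. The 3 tumours of the first, all tibial and Rbfl/+ like shRNA OS replicate 3, had macrophage scores of 0.64, 0.79 and 0.87, against -0.98 to -0.05 in the other 5. Their osteoclast scores were -1.34, -0.64 and -0.74, against 0.17 to 0.85. These scores were compared after the split was seen. That split was picked as the highest of 56, and what underlies it was not tested.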
